A study of Mus musculus with 15 samples.

How the data were processed

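RNA was measured in the ileum, the last part of the small intestine, of adult C57BL/6 mice raised germ-free. Per the labels' protocols, each mouse received 200 µl of bacteria or of sterile phosphate-buffered saline (PBS) by gavage, and tissue was taken 21 days later. The bacteria were Lactobacillus rhamnosus GG (LGG), a strain sold as a probiotic, or Ruminococcus gnavus (RG), a Clostridia-class member of the human gut microbiota. Each of the 3 groups held 5 mice and each mouse gave 1 library, so replicates were separate animals. The labels give no cage, litter, sex, batch or time of day, and no sex-linked gene was listed, so none of these could enter a model.

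Per the labels' protocols, RNA was extracted with a column kit after tissue lysis and libraries were made with a NEBNext Ultra II kit. The submitters' processing notes name GRCm38, also called mm10, as the genome build. The aligner, the counting tool and its handling of shared reads are not given in the sources used here. The authors deposited 1 table of TPM (transcripts per 1e+06 transcripts, in which each value is scaled by transcript length and by the sum over all transcripts of a library). It listed 4178 genes in 15 libraries. The deposited TPM of a library summed to 480498 to 660553, or 48.0 to 66.1% of all TPM, so the table held part of the genes on which TPM was computed. The rule that chose these genes was not stated. TPM holds no sequencing depth, so depth is unknown, and no counting error or detection limit can be given for any value.

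Gene identifiers were matched to GENCODE mouse release 21, an annotation of GRCm38. Of the 4178 identifiers, 4173 were found, and 4159 of these were protein coding. Coordinates are 1-based and on GRCm38. Transcript length and GC content came from the same annotation.

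The design fixed before the data were examined foresaw read counts and named limma as the fallback for normalized values. Since the values were TPM, limma-trend with robust shrinkage (limma 3.58.1 in R 4.3.3) was fitted to log2(TPM + 1). A gene was tested if its TPM was at least 1 in 5 or more libraries, which left 3530 genes tested and 648 not tested. All 15 libraries entered 1 model with 3 groups, which share 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are differences on the log2(TPM + 1) scale with their standard error (SE), and they understate the change of genes with low TPM. Mean TPM is given ± SD over the 5 mice of a group. Any adjusted p-value of a single gene below is limma's.

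Before the data were examined, 45 gene lists with 812 members were fixed, covering pathways, cell types and RNA quality. A list was tested if at least 5 of its members were tested, which held for 27 lists. Lists were tested with camera (limma), which compares the members with all other genes tested, at a preset correlation between genes of 0.01 and with adjustment over the lists of a comparison. Because camera is relative, a list can be called lower while its members are near 0. The same test was run with the correlation estimated for each list, and fry (limma) tested whether members move one way on balance, without reference to other genes. Counts of changed members are given over all genes tested and adjusted over the list alone.

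The rule for named genes was also fixed then. It took, for each comparison, the 12 largest increases and the 12 largest decreases past the threshold with a mean TPM of at least 1, up to 4 members of smallest p from each list that passed or held at least 2 changed members, and a set of sentinel genes. As run, it took up to 4 members where camera passed and up to 2 from the other such lists. It left out symbols given to predicted genes and clones and the variable segments of antigen receptors. It yielded 61 genes for RG against PBS, 102 for LGG against PBS and 113 for RG against LGG, and the text names part of them and gives the rest as counts. The sentinels Saa1, Fut2, Slc10a2, Fabp6, Fgf15, Tph1, Igha, Cyp1a1, Apoa4 and Muc2 were not among the genes listed.

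Library measures were compared between groups with two-sided exact permutation tests over 252 splits of 5 against 5 mice. These were the summed TPM of the listed genes, genes with a TPM above 0, and the share of all TPM in the 10 highest genes and in mitochondrially encoded genes. The shares of ribosomal protein genes and of defensins were added after the data were seen. The overlap of the effects of RG and LGG, which share their PBS libraries, was set against 100 simulations of unchanged groups. It was also set against 20 fits on split PBS libraries and against the overlap of independent lists.

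The fit was tested on simulated data with 3530 genes, of which 100 changed 1.5-fold and 100 changed 2-fold. For RG against PBS it recovered 39.0 and 82.0% of these, for LGG against PBS 29.0 and 69.0%, and for RG against LGG 45.0 and 77.0%. Of all genes called in these simulations, 6.92, 7.55 and 6.87% were false. The simulated noise was drawn separately for each gene, whereas genes of the real libraries are correlated, so these rates need not hold for the real data.

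Alternatives planned before the data were examined were median-of-ratios and upper-quartile scaling, pseudocounts of 0.1 and 5, no filter on low values, only the 2 groups compared in the fit, shrinkage that is not robust, the mouse number as a replicate block, and each library left out in turn. Alternatives added after the data were seen were sample quality weights, a filter at a TPM of 5, removal of a trend on transcript length and GC content (a spline with 4 degrees of freedom per library, keeping the mean of each library), 3 libraries left out together, camera with median-of-ratios scaling, and a zero point at the midpoint of a sparse window of ratios. Median-of-ratios and upper-quartile scaling took their factors from the listed genes and assume that most of these are unchanged. This may fail if genes were listed by the size of a difference. Count-based tests and a sex term were planned and could not be run. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and plots. Random draws used seed 1.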

Results

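Ileal RNA was profiled in germ-free mice that received PBS, RG or LGG, with 5 mice in each group, to compare the germ-free ileum with the ileum colonized by a single bacterial species. Values were TPM for a list of genes, of which 3530 were tested, and sequencing depth is unknown. Rank correlations between mice of a group, taken across genes, were 0.964 to 0.988 for PBS, 0.876 to 0.988 for RG and 0.905 to 0.988 for LGG. The first principal component held 64.8% of the variance and placed all 5 LGG libraries at 34.3 or more, the 5 PBS libraries at -27.0 or less, and the RG libraries between -24.2 and 6.98.

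The listed genes summed to 63.8% ± 2.96 of all TPM in PBS, 61.3% ± 3.21 in RG and 50.1% ± 1.97 in LGG (SD, n = 5). The difference between LGG and PBS passed (exact permutation p = 0.00794, adjusted p = 0.0159), and that between RG and PBS did not (exact p = 0.254, adjusted p = 0.339). Alpha-defensins are antimicrobial peptides stored by Paneth cells. Those among the listed genes held 12.2% ± 1.67 of all TPM in PBS, 12.9% ± 1.48 in RG and 1.19% ± 1.04 in LGG. Their share was lower in LGG than in PBS (exact p = 0.00794, adjusted p = 0.0143) and did not pass for RG (exact p = 0.508, adjusted p = 0.610). Ribosomal protein genes held 18.2% ± 2.10 in PBS, 13.4% ± 1.29 in RG and 8.44% ± 1.08 in LGG, and both colonized groups were lower than PBS (exact p = 0.0238 and 0.00794, adjusted p = 0.0390 and 0.0143). The mitochondrially encoded share was 7.75% ± 1.68 in PBS, 9.55% ± 5.29 in RG and 6.37% ± 0.680 in LGG, with no difference that passed (exact p of 0.119 or more), and RG mouse 5 alone held 18.4%. Across 3527 genes, which are not independent replicates, transcript length had a Spearman correlation of 0.395 with the RG effect and 0.405 with the LGG effect.

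With RG, some genes of mucosal defence and many of the digestive brush border were higher than in PBS. Nos2, which encodes inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), was at 9.79 ± 4.26 TPM in RG and 1.62 ± 0.552 in PBS, a log2 difference of 1.97 (SE 0.306, adjusted p = 0.00872, n = 5). Pigr, the receptor that carries immunoglobulin A into the lumen, rose by 1.44 (215 ± 130 against 82.0 ± 56.6 TPM, adjusted p = 0.0374). Reg3g, which encodes a lectin that kills Gram-positive bacteria (chromosome 6, 78466269 to 78468872), rose by 1.24 (2125 ± 1624 against 723 ± 142 TPM, adjusted p = 0.0482), and Reg3b differed by 0.50 without passing (adjusted p = 0.351). Of 9 tested defence genes these 3 rose by both adjustments, and the list did not pass camera (median 0.56, adjusted p = 0.594). Anpep, an aminopeptidase of the brush border (chromosome 7, 79821803 to 79861059), rose by 0.94 (1340 ± 211 against 702 ± 131 TPM, adjusted p = 0.0115).

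Of the 19 tested genes for sugar and peptide digestion and uptake, 12 rose with RG and none fell, and 15 rose when adjusted over the list alone. Besides Anpep they included Dpp4 (0.98), a peptidase that removes dipeptides from the ends of peptides, the aminopeptidase Enpep (0.75) and the amino acid transporter Slc6a20a (0.85). The list had a median of 0.86 and passed camera (adjusted p = 0.000622), but adjusted p = 0.773 with an estimated correlation. With median-of-ratios scaling 4 of the digestion genes rose (median 0.52) and none of the MHC class I genes (limma, median 0.46), and with upper-quartile scaling 5 and 2 rose. Of 10 tested genes of MHC class I presentation, which shows peptides to CD8 T cells, 6 rose and 9 rose when adjusted over the list alone. Examples were H2-Q4 (0.95), the peptide-loading chaperone Tapbp (0.81), H2-T3 (0.81) and the peptide-trimming enzyme Erap1 (0.70). This list had a median of 0.80 and passed camera at adjusted p = 0.0454, with adjusted p = 0.850 with an estimated correlation. RG mouse 2, which stood apart in T cell genes such as Cd3d (45.5 TPM), was highest for Tap1 (51.2 against 7.40 to 15.5 TPM in the other RG mice), H2-Q4 (86.4 against 16.5 to 35.2) and H2-D1 (1281 against 316 to 679), while H2-K1 in RG mice 4 and 5 (462 and 493 TPM) lay within the PBS range of 328 to 605. Without RG mouse 2 the list kept its camera call (adjusted p = 0.0335), but H2-Q4 was at 0.60 (adjusted p = 0.0594). With LGG all 10 members rose by both adjustments (median 1.71, camera adjusted p = 0.0675), and 8 were lower in RG than in LGG (mean -0.913, camera adjusted p = 0.167). In RG against PBS the camera call was lost without PBS mouse 4, RG mouse 1, LGG mouse 2 or LGG mouse 4 (adjusted p = 0.0862, 0.0750, 0.0530 and 0.0709).

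Clock-controlled genes were also higher in RG. Of 6 tested members of the circadian clock list 4 rose and none fell, over all genes and adjusted over the list alone, and these were the clock output factors Dbp (1.83, SE 0.276) and Tef (1.14) and the transcriptional repressors Nr1d1 (1.32) and Nr1d2 (1.22). The list as a whole did not pass camera (adjusted p = 0.0568). Among the other largest increases were the sugar transporter family member Slc5a4a (1.44), the carboxylesterase Ces2a (1.33), the nucleoside transporter Slc28a2 (1.29), Slc23a4 (1.25), the cytochrome P450 Cyp3a25 (1.24) and H2-Q5 (1.18). The serotonin transporter gene Slc6a4 rose by 0.85 (adjusted p = 0.0211), and without PBS mouse 3 its adjusted p was 0.0670.

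On the deposited scale fewer genes were lower in RG than higher (144 against 804), whereas with median-of-ratios scaling 570.0 were lower and 42 higher. The largest decreases were in Scgb2b7 (-0.95), the calcium-binding protein genes S100a6 (-0.88) and S100a14 (-0.81), the chaperone Fkbp11 (-0.80), Tmem256 (-0.75), Ctxn3 (-0.71), Pagr1a (-0.70), the nucleoside diphosphate kinase Nme2 (-0.66), Fmc1 (-0.66), the cytochrome oxidase genes Cox4i1 (-0.65) and Coa6 (-0.65), and Rpl41 (-0.65). Of 78 ribosomal protein genes 34 were lower and none higher. These calls rest on single libraries, since of all genes tested 0 were lower without PBS mouse 3 and 2 without PBS mouse 5. The goblet cell list, markers of mucus-secreting cells, passed camera downwards (median -0.50, adjusted p = 0.0226, and adjusted p = 0.773 with an estimated correlation), and without RG mouse 2 its adjusted p was 0.0566. Of its 5 tested members 1 fell, the goblet cell peptide gene Spink4 (-0.64, adjusted p = 0.0412, and -0.41 with adjusted p = 0.0692 without PBS mouse 1), and 2 fell when adjusted over the list alone, while Tff3 (-0.47), Agr2 (-0.54) and Ccl9 (-0.50) did not pass. The smooth muscle list also passed camera downwards (median -0.45, adjusted p = 0.00619, and adjusted p = 0.773 with an estimated correlation) although none of its 8 members passed over all genes or adjusted over the list alone, with Tagln at -0.61, Des at -0.48, Synm at -0.45 and Synpo2 at -0.39 on the deposited scale. With median-of-ratios scaling 5 of the 8 were lower (median -0.79). PBS mouse 1 was highest for Tagln (1306 against 434 to 626 TPM in the other PBS mice) and Des (396 against 112 to 251.8), and without it Tagln was at -0.33 and Des at -0.23.

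The Paneth cell list did not pass between RG and PBS. Lyz1, the lysozyme of Paneth cells (chromosome 10, 117287797 to 117292868), was at 7697 ± 2643 TPM in RG and 7195 ± 1281 in PBS (log2 difference 0.03, SE 0.477, adjusted p = 0.961), and this difference was -0.31 with median-of-ratios scaling and -0.25 with upper-quartile scaling. Of the 18 tested members of the list only Nupr1, a stress-response gene (0.56), passed over all genes, and none passed adjusted over the list alone. Some genes were nevertheless higher in most RG mice without passing, Mptx2 at 870.2 ± 253 against 309 ± 175 TPM (1.61, adjusted p = 0.0766) and Defa39 at 1471 ± 394 against 829.5 ± 182 TPM (0.81, adjusted p = 0.365). The median of the list was 0.04 and its mean 0.103, while camera ranked it below the other genes without passing (adjusted p = 0.371).

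In all, 948 of 3530 genes changed with RG (limma, adjusted p under the threshold), 804 higher and 144 lower, and 1758 had an unadjusted p under 0.05. The groups did not overlap in 554 genes, 15.7% of those tested, where chance gives 0.794%. The median of all genes tested was 0.38, and it was 0.07 with median-of-ratios scaling and 0.12 with upper-quartile scaling. With these scalings 42 genes were higher and 570 lower, and 115 higher and 468 lower, so that 6.86 and 19.7% of the changed genes were higher, against 84.8% on the deposited scale. Since both scalings assume that most listed genes are unchanged, which may fail here, the main direction is not settled by either scale. Nos2 (1.76 and 1.82), Dbp (1.61 and 1.66) and Anpep (0.60 and 0.66) passed with both scalings, whereas Reg3g (0.90 and 0.96) and Pigr (1.11 and 1.16) did not. The count depended on single libraries. It was 437 without PBS mouse 1, 40.0 without PBS mouse 3, 624 without PBS mouse 4, 124 without PBS mouse 5, 150.0 without RG mouse 2, 177 without RG mouse 3 and 1594 without RG mouse 4. Of 52 named genes that passed, 9 passed in each fit with 1 library left out: Nos2, Dbp, Nr1d1, Nr1d2, Anpep, Slc6a20a, Enpep, the Wnt target Axin2 and the amino acid transporter Slc6a19. Reg3g had log2 differences of 0.86 to 1.34 in the 10 such fits in which it did not pass, those without any 1 of the 5 PBS mice, RG mouse 1, 2 or 3, or LGG mouse 1 or 3, the lowest of them without RG mouse 2. Pigr did not pass without PBS mouse 3, 4 or 5 or RG mouse 2 or 3 (adjusted p = 0.105, 0.0577, 0.0706, 0.0965 and 0.0659). With the length and GC trend removed the count was 315.

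Some libraries stood apart in genes of other tissues, which were chosen after their values were seen. In RG mouse 2 the T cell genes Cd3d (45.5 TPM) and Lat (51.3 TPM) and the chemokine gene Ccl5 (169 TPM) were above the other RG mice, which reached 4.19, 2.25 and 29.1 TPM, and Reg3g was highest in this mouse at 4819.6 TPM. RG mouse 5 was the single library with TPM above 0 for the kidney gene Kap (8.21 TPM), and PBS mouse 1 had the liver gene Alb at 556 TPM against 56.7 to 157 in the other PBS mice. With PBS mouse 1, RG mouse 2 and RG mouse 5 left out together, no gene passed for RG against PBS (limma, lowest adjusted p = 0.107), and 965 had an unadjusted p under 0.05.

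**Figure D1:**
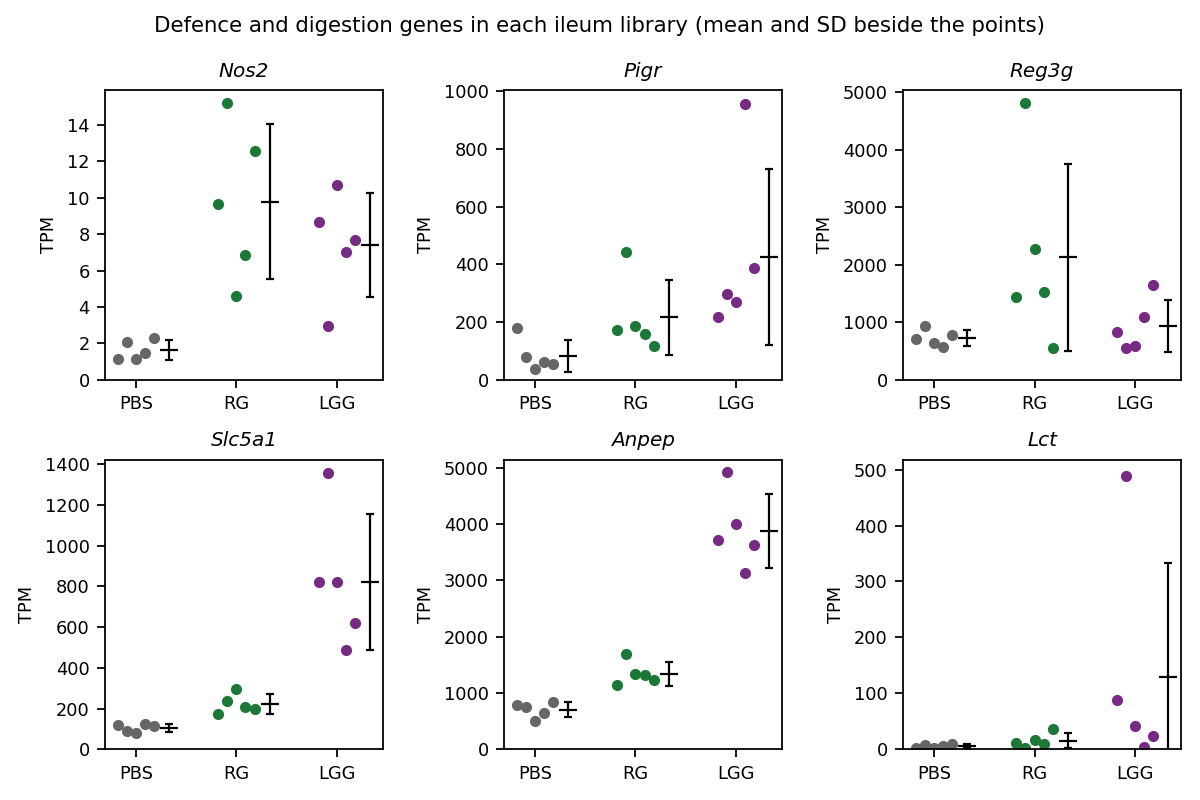
TPM of 3 defence genes (Nos2, Pigr, Reg3g) and 3 digestion genes (Slc5a1, Anpep, Lct) in each ileum library, on linear axes from 0, with 1 point per mouse and the mean and SD of the 5 mice beside the points. Nos2 lies between 4.62 and 15.2 TPM in RG and between 1.12 and 2.32 TPM in PBS, and Anpep averages 3882 TPM in LGG.

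LGG colonization was accompanied by low Paneth cell transcripts and high transcripts of enterocyte function. Lyz1 fell from 7195 ± 1281 TPM in PBS to 765 ± 572 in LGG, a log2 difference of -3.62 (SE 0.477, adjusted p = 4.85e-06, n = 5). Mmp7, the protease that activates defensins, fell by 3.10 (47.8 ± 25.2 against 364 ± 29.2 TPM), and Ang4, a bactericidal ribonuclease, fell by 4.47 (93.2 ± 81.2 against 1773 ± 1476 TPM). Slc5a1, the sodium-glucose transporter SGLT1 (chromosome 5, 33104219 to 33162870), rose from 106 ± 18.9 to 820.5 ± 332 TPM (2.87, SE 0.231, adjusted p = 6.53e-08).

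All 18 tested members of the Paneth cell list fell, over all genes and adjusted over the list alone, with a median of -3.79 (camera adjusted p = 1.77e-12, and adjusted p = 0.626 with an estimated correlation). They fell with both other scalings, with a median of -4.65 for median-of-ratios scaling, and with the length and GC trend removed, with a median of -1.75. The defensin Defa30 was at 952 ± 740.0 TPM in LGG and 12393 ± 1631 in PBS (-4.16). Defa41 (-5.97), Defa36 (-5.80), Defa3 (-4.94), Defa33 (-4.68), Defa32 (-4.57), Defa23 (-4.52), Defa2 (-4.08), Defa37 (-4.07), Defa34 (-4.05) and the mucosal pentraxin Mptx2 (-4.23) were among the 12 largest decreases with Ang4 and Defa30. Values of single defensins are uncertain, because these genes are close copies whose reads could be split between them. Defa31 (chromosome 8, 21191614 to 21192549) was the 1 defensin among the largest increases. It was at 648 ± 378 TPM in LGG, 56.5 TPM in PBS mouse 4 and listed at 0 in the other PBS mice. All 347 of its 31-base words also occur in Defa23, so the fall of Defa23 may be overstated. Genes of colonic epithelium, a tissue without Paneth cells, rose in 3 of 6 by both adjustments (median 1.59, camera adjusted p = 0.825), with the chloride exchanger Slc26a3 at 2.08 and Car4 at 1.72, and 2 rose with median-of-ratios scaling. LGG mouse 4, the lowest in Lyz1 (162 TPM) and Defa30 (176 TPM), had Slc26a3 at 418 TPM against 64.2 to 99.5 in the other LGG mice.

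**Figure D2:**
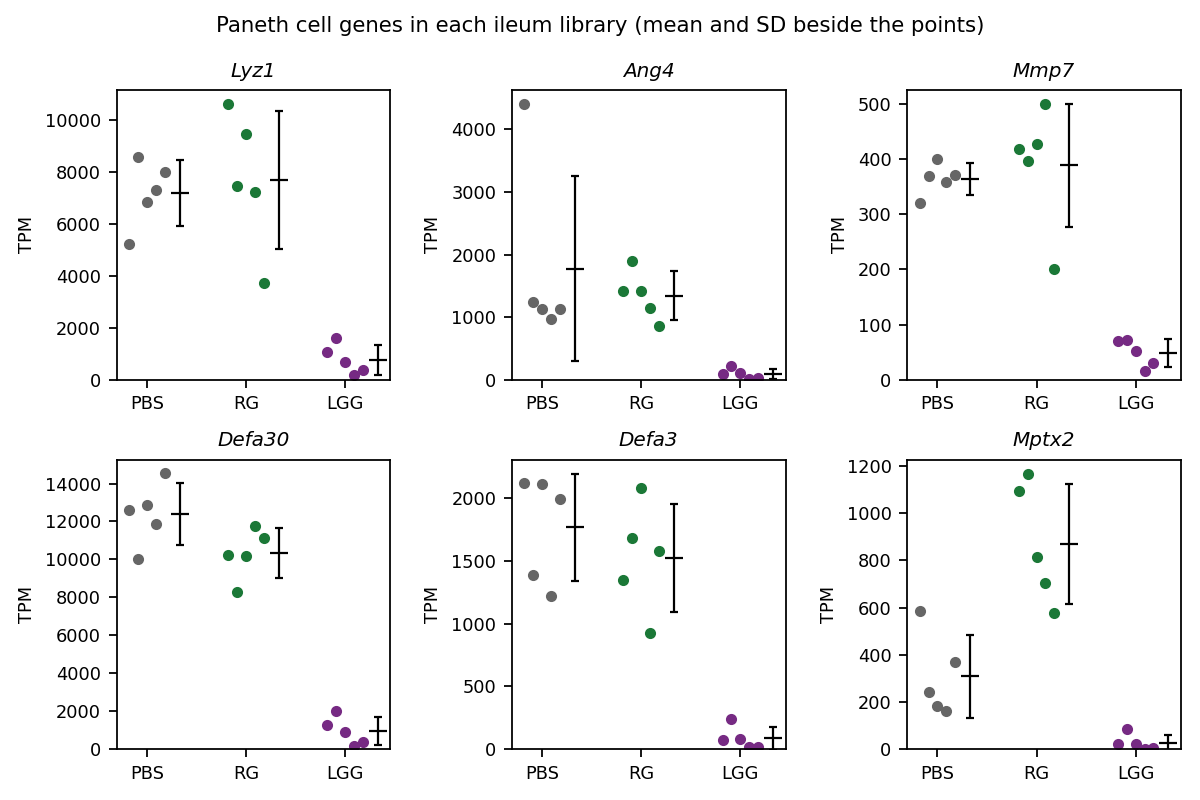
TPM of 6 Paneth cell genes in each ileum library, on linear axes from 0, with 1 point per mouse and the mean and SD of the 5 mice beside the points. Lyz1, Ang4, Mmp7, Defa30, Defa3 and Mptx2 are lower in each LGG library than in each PBS library, and Ang4 in PBS mouse 1 stands at 4409 TPM.

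Goblet cell genes fell as well. All 5 tested members fell, over all genes and adjusted over the list alone (median -1.39, camera adjusted p = 0.00182, and adjusted p = 0.626 with an estimated correlation). Spink4 fell by 2.06, the mucin-folding disulfide isomerase Agr2 by 1.57, the chemokine Ccl9 by 1.39 and the trefoil factor Tff3 by 1.34. With the length and GC trend removed, Spink4 and Tff3, which have short transcripts, were at 0.08 and 0.37.

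Each of the 19 tested digestion genes rose with LGG, over all genes and adjusted over the list alone (median 2.27, camera adjusted p = 0.00104, and adjusted p = 0.626 with an estimated correlation). They included lactase, Lct (3.03), the fructose transporter Slc2a5 (2.96), the peptidase Ace (2.94), the glucose transporter Slc2a2 (2.72) and Anpep (2.47, 3882 ± 658 TPM). Lct was at 3.88 without LGG mouse 4 and at 2.17 without LGG mouse 2 (adjusted p = 0.000207 and 0.0190), and LGG mouse 4 had 3.32 TPM of Lct and 6.11 of Slc2a2, within the PBS range of 1.61 to 9.49 and 1.87 to 7.69, and 28.1 of Slc2a5, where the highest PBS mouse had 28.0. All 9 tested tight junction genes rose by both adjustments (median 1.59, camera adjusted p = 0.0307, and adjusted p = 0.626 with an estimated correlation), among them the adhesion gene Cdh1 (2.28), Patj (1.37) and Marveld2 (1.28). Of 14 xenobiotic response genes 13 rose by both adjustments (median 1.83), with Ces2a at 2.82, the efflux pump Abcb1a at 2.40 and the cytochrome P450 Cyp3a13 at 2.23. Of 10 fatty acid oxidation genes 9 rose by both adjustments (median 1.70), with Hadha at 1.79 and Ehhadh at 1.75. Both of these lists had a camera adjusted p of 0.0471, adjusted p = 0.626 with an estimated correlation, and an adjusted p of 0.0602, 0.0537 and 0.0541 without PBS mouse 4, RG mouse 2 and RG mouse 4. The median of each of these 4 lists stayed above 0 with median-of-ratios scaling, at 1.42, 0.73, 0.97 and 0.86. Other large increases were in the phospholipase Plb1 (3.60), Slc5a4a (3.24), the intestinal sphingomyelinase Enpp7 (3.22), Fam151a (3.08) and the ceramidase Asah2 (2.82). Without LGG mouse 2 Plb1, Fam151a and Asah2 were at 2.86, 2.40 and 2.11, and without LGG mouse 4 Plb1 and Fam151a were at 4.52 and 3.91, and each of these passed.

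**Figure D3:**
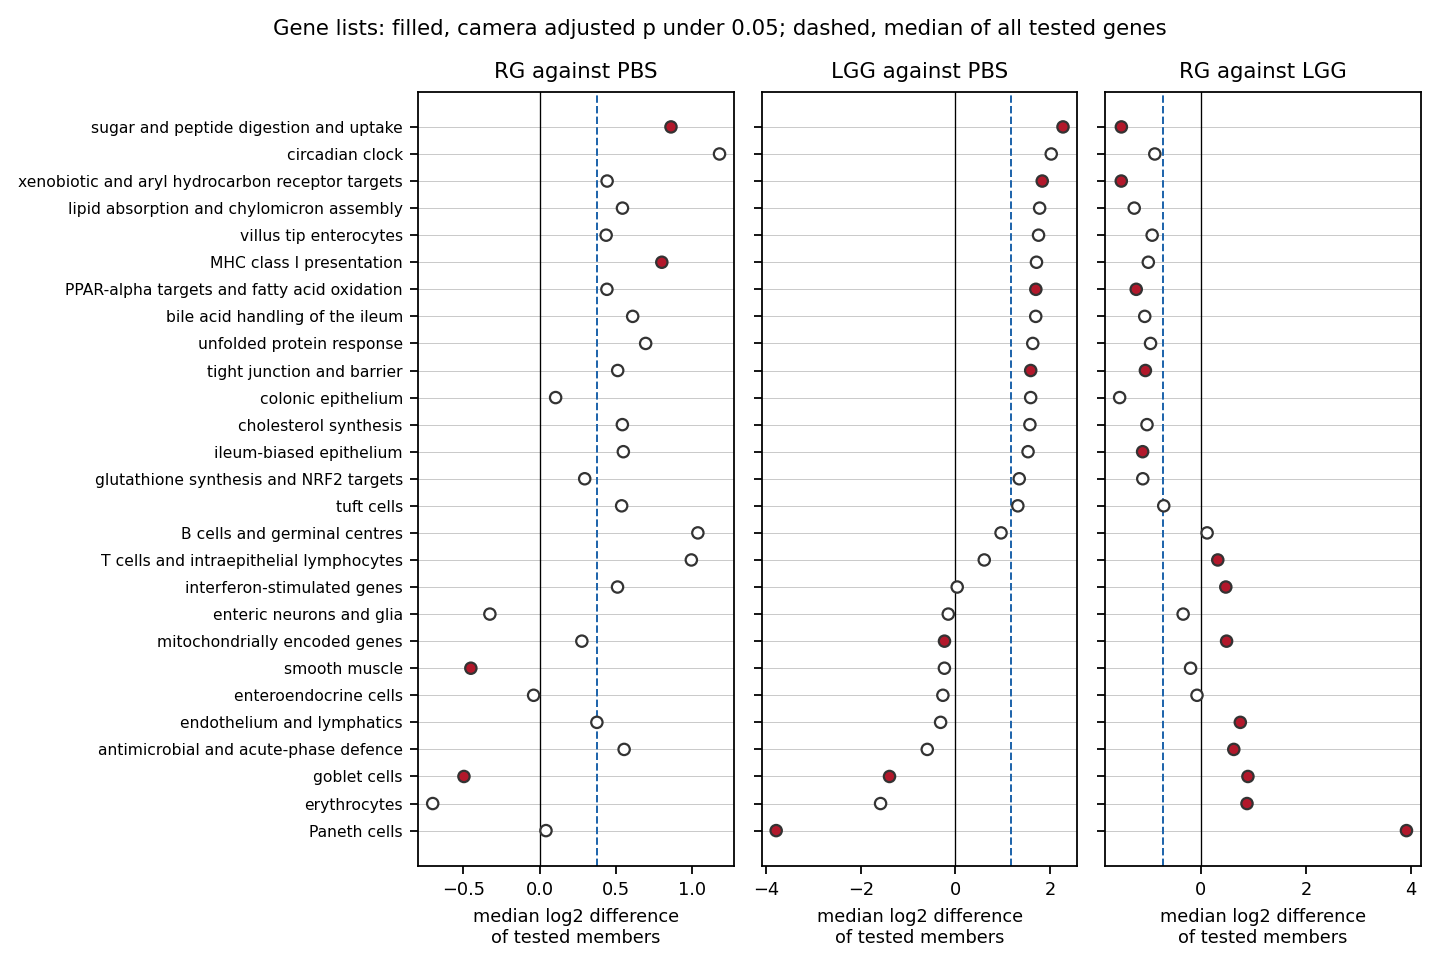
Median log2 difference of the tested members of each gene list in the 3 comparisons, with 1 point per list, filled where the camera adjusted p is under 0.05, and a dashed line at the median of all genes tested. The Paneth cell list lies at a median of -3.79 in LGG and 0.04 in RG, and the digestion list lies at 2.27 in LGG and 0.86 in RG.

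The clock output gene Dbp (chromosome 7, 45705088 to 45710203) rose by 3.90 (SE 0.276, 44.0 ± 18.1 against 1.90 ± 0.665 TPM, adjusted p = 2.84e-08). Of 6 tested clock genes 5 rose by both adjustments, among them Nr1d1 (2.75), Tef (2.28) and Nr1d2 (1.77), whereas Nfil3, a repressor named here after its values were seen, was at -0.60 without passing (adjusted p = 0.111). The list did not pass camera (median 2.02, adjusted p = 0.157). Nr1d1 lay between 6.37 and 18.5 TPM in PBS, 20.8 and 48.4 in RG and 73.2 and 118 in LGG. Defence genes were split, and of 9 tested 2 rose and 3 fell by both adjustments (median -0.59, camera adjusted p = 0.118). Pigr rose by 2.36 and Nos2 by 1.62, while Reg3g (0.27, adjusted p = 0.580) and Reg3b (-0.69, adjusted p = 0.175) did not pass. Slc6a4 rose by 2.04.

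**Figure D4:**
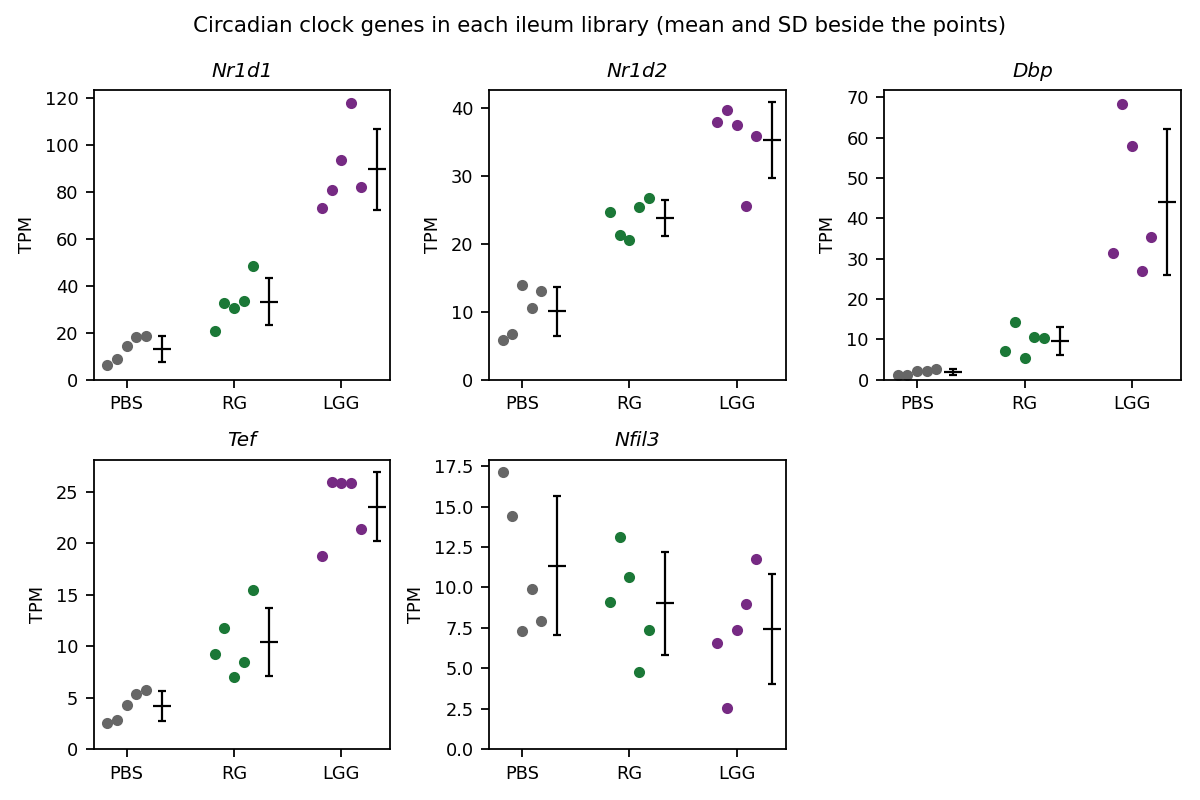
TPM of the clock genes Nr1d1, Nr1d2, Dbp, Tef and Nfil3 in each ileum library, on linear axes from 0, with 1 point per mouse and the mean and SD of the 5 mice beside the points. Dbp averages 1.90 TPM in PBS, 9.56 TPM in RG and 44.0 TPM in LGG.

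The mitochondrially encoded list passed camera downwards (median -0.23, adjusted p = 0.0490, and adjusted p = 0.657 with an estimated correlation), and none of its 11 members passed by either adjustment, with mt-Co3 at -0.48 and mt-Nd2 at -0.34. Its call was lost without PBS mouse 2, PBS mouse 4, RG mouse 4, LGG mouse 2 or LGG mouse 5 (adjusted p = 0.0512, 0.0887, 0.0541, 0.0660 and 0.0627), and its direction turned with the length and GC trend removed (median 1.52), while with median-of-ratios scaling all 11 were lower (median -1.10). Of 78 ribosomal protein genes 71 were lower in LGG, with a median of -1.17.

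In all, 2514 genes changed with LGG, 1932 higher and 582 lower, and 2567 had an unadjusted p under 0.05. The groups did not overlap in 2396 genes, 67.9% of those tested, where chance gives 0.794%. The median of all genes tested was 1.17, and it was 0.40 with median-of-ratios scaling and 0.30 with upper-quartile scaling. With these scalings 1729 genes were higher and 1391 lower, and 1467 higher and 1388 lower, so that 55.4 and 51.4% of the changed genes were higher, against 76.8% on the deposited scale. Of 1863 genes with a mean TPM of at least 20, only 6 had a log2 ratio of LGG to PBS between 0.16 and 0.96, where an even spread would give 392, and 1141 lay above and 715 below. In the ratio of RG to PBS, 1090 of these genes lay in the same window. The counts therefore describe the listed genes, not the whole transcriptome. The chance rate of 0.794% holds only for genes not chosen by their difference between LGG and PBS, so the excess over it may come from the listing. The other comparisons share libraries with LGG against PBS, so this limit extends to them.

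**Figure D5:**
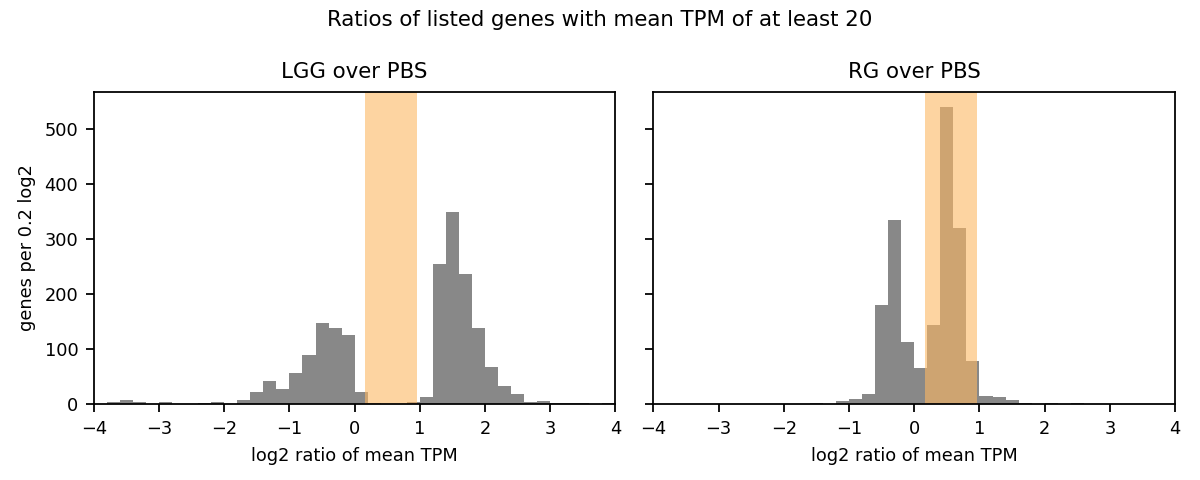
Number of genes by log2 ratio of mean TPM, LGG over PBS and RG over PBS, for the 1863 genes with a mean TPM of at least 20, in bins of 0.2 with the axis limited to 4 on either side of 0. The LGG panel has a gap between 0.16 and 0.96 that holds 6 genes, and the RG panel holds 1090 genes there.

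RG and LGG colonized mice were compared directly, which tests whether the effects differ. Paneth cell genes were far higher in RG, with Lyz1 at 7697 ± 2643 against 765 ± 572 TPM (3.65, SE 0.477, adjusted p = 2.84e-05, n = 5). All 18 tested members were higher by both adjustments (median 3.92, camera adjusted p = 1.48e-20, and adjusted p = 0.298 with an estimated correlation), including Defa3 (4.71), Defa23 (4.64), Defa39 (4.37), Ang4 (4.29), Defa20 (4.20) and Mmp7 (3.14). Outside the list, Defa41 was higher by 6.25, Mptx2 by 5.84, Defa36 by 5.66, Defa32 by 4.75, Defa33 by 4.74, Defa34 by 4.59 and Defa37 by 4.40. Defa31 was listed at 0 in all 5 RG mice and at 648 ± 378 TPM in LGG, so no fold is given.

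Of 9 tested defence genes 4 were higher in RG and none lower, by both adjustments (median 0.63, camera adjusted p = 0.00408, and adjusted p = 0.374 with an estimated correlation). These were the intelectin Itln1 (2.50), the phospholipase gene Pla2g2a (2.04), Reg3b (1.19, adjusted p = 0.0287) and the siderophore-binding protein gene Lcn2 (0.63). Among LGG mice, Itln1 (80.8 and 189 TPM) and Pla2g2a (2.51 and 1.65 TPM) were lowest in mice 4 and 5, as was Lyz1. Reg3b and Lcn2 were lowest in LGG mouse 2. Whether the calls of Itln1 and Pla2g2a are separate from the Paneth cell result was not tested. The call of Reg3b was lost without RG mouse 2, RG mouse 4, LGG mouse 1 or LGG mouse 2 (adjusted p = 0.0910, 0.0625, 0.0524 and 0.0802), and Reg3g was at 0.97 without passing (adjusted p = 0.0680). Goblet cell genes were higher in RG in 4 of 5 members, and in 5 of 5 adjusted over the list alone (median 0.90, camera adjusted p = 0.000806, and adjusted p = 0.298 with an estimated correlation), with Spink4 at 1.42, Agr2 at 1.04, Ccl9 at 0.90 and Tff3 at 0.87. Spink4 and Tff3 were at -0.20 and -0.38 with the length and GC trend removed.

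Enterocyte lists were lower in RG than in LGG. Of the 19 digestion genes 18 were lower by both adjustments (median -1.52, camera adjusted p = 0.000806, and adjusted p = 0.545 with an estimated correlation), with Slc5a1 at -1.81, Ace at -1.81 and Anpep at -1.53. Of 14 xenobiotic genes 12 were lower by both adjustments (median -1.52, camera adjusted p = 0.0149, and adjusted p = 0.586 with an estimated correlation), with Abcb1a at -1.94 and Cyp2c65 at -1.84. All 9 tight junction genes, with Cdh1 at -1.67, and 9 of 10 fatty acid oxidation genes were lower by both adjustments (medians -1.06 and -1.23, camera adjusted p = 0.0112 and 0.0149, and adjusted p = 0.545 and 0.586 with an estimated correlation). Of 8 genes of the ileum-biased epithelium 7 were lower by both adjustments, with the vitamin B12 receptor gene Cubn at -1.57 (list median -1.11, camera adjusted p = 0.0323, and adjusted p = 0.374 with an estimated correlation). With upper-quartile scaling 10 digestion, 8 xenobiotic, 4 tight junction and 3 ileum-biased genes were lower. Without RG mouse 2 the xenobiotic and ileum-biased lists had an adjusted p of 0.0878 each. Other large decreases were in Dbp (-2.07), the sodium-proton exchanger Slc9a3 (-2.06), the carboxylesterase Ces1g (-2.05), Selenbp1 (-1.90), the zinc receptor Gpr39 (-1.85), the glucuronosyltransferase Ugt1a7c (-1.84) and Slc5a4a (-1.79). The call of Selenbp1 was lost without RG mouse 1, 2, 4 or 5 or LGG mouse 5 (adjusted p = 0.0711, 0.0569, 0.0621, 0.0808 and 0.0631), and without LGG mouse 4, which held 2088 TPM against 69.2 to 313 in the other LGG mice, it was at -1.07 (adjusted p = 0.0454). LGG mouse 4 was also highest for Slc9a3 (67.1 against 4.51 to 26.3 TPM in the other LGG mice), Ces1g (307 against 14.3 to 63.5) and Cyp2c65 (505 against 75.5 to 154). RG mouse 3, at 6.65 TPM of Slc9a3, lay above LGG mice 1, 3 and 5. Nr1d1 (-1.43, adjusted p = 0.000251) and Slc6a4 (-1.19, adjusted p = 9.68e-05) were lower as well, and of the 6 clock genes 5 were lower by both adjustments (median -0.88, camera adjusted p = 0.295).

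Other lists passed camera upwards with few changed members. Of 5 genes of endothelium and lymphatics 2 were higher by both adjustments, Mmrn1 (0.80) and the lymphatic growth factor receptor gene Flt4 (0.75, and 0.49 without RG mouse 2) (list median 0.75, camera adjusted p = 0.0102, and adjusted p = 0.545 with an estimated correlation). The mitochondrially encoded list (median 0.49, adjusted p = 0.000814, and adjusted p = 0.586 with an estimated correlation) had none of 11 members passing by either adjustment, with mt-Nd6 at 0.69 (0.36 without RG mouse 5), and its direction turned with the length and GC trend removed. The T cell list (median 0.32, adjusted p = 0.0225, and adjusted p = 0.586 with an estimated correlation) had none of 11 passing, and without RG mouse 2, which held Cd3d at 45.5 TPM, its adjusted p was 0.709. The erythrocyte list (median 0.88, adjusted p = 0.0464, and adjusted p = 0.586 with an estimated correlation) had none of 5 passing, with Hbb-bs at 1.24, and lost its call without RG mouse 1, 2 or 4 or LGG mouse 2 or 3 (adjusted p = 0.106, 0.0742, 0.0605, 0.0929 and 0.0541).

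Interferon-stimulated genes divided in RG against LGG. Mx1, an antiviral GTPase, was higher (0.68, adjusted p = 0.0332), while the RNA sensors Ddx58 (-0.58) and Ifih1 (-0.85) and the synthetase gene Oas3 (-0.86) were lower. Of 11 members 1 was higher and 3 lower, and none higher and 2 lower when adjusted over the list alone, yet the list passed camera upwards (median 0.47, adjusted p = 0.0464, and adjusted p = 0.586 with an estimated correlation). With median-of-ratios scaling 8 members were higher and 1 lower, and with upper-quartile scaling 8 were higher and none lower. The call of the list was lost without PBS mouse 2, RG mouse 1, 2 or 5 or LGG mouse 1, 2 or 4 (adjusted p = 0.0504, 0.0524, 0.107, 0.145, 0.0607, 0.0522 and 0.0687). Mx1 did not pass without RG mouse 5 or LGG mouse 1, 2 or 4 (adjusted p = 0.0632, 0.0534, 0.0558 and 0.0745), nor Ddx58 without RG mouse 1, 3 or 4 or LGG mouse 3 or 5 (adjusted p = 0.0535, 0.0742, 0.0739, 0.0539 and 0.0568). Jchain, which joins immunoglobulin A into dimers, was higher in RG by 1.53 (adjusted p = 0.0172), with adjusted p = 0.0649 without RG mouse 2, and Slc2a2 was lower by 1.78 (adjusted p = 0.0152), with adjusted p = 0.0604 without RG mouse 2.

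In all, 2176 genes differed between RG and LGG, 289 higher and 1887 lower in RG, and 2265 had an unadjusted p under 0.05. The groups did not overlap in 1430.0 genes, 40.5% of those tested, where chance gives 0.794%. The median of all genes tested was -0.72, and it was -0.23 with median-of-ratios scaling and -0.08 with upper-quartile scaling. With these scalings 1088 genes were higher and 1057 lower, and 1242 higher and 554 lower, so that 50.7 and 69.2% of the changed genes were higher, against 13.3% on the deposited scale. Ribosomal protein genes were higher in RG in 61 of 78.

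Some genes changed with both bacteria. Nos2, Dbp, Nr1d1, Anpep, Slc5a1, Pigr and Slc6a4 rose with both RG and LGG, whereas Lyz1 and Mmp7 fell with LGG and differed between LGG and RG. Reg3g passed for RG and not for LGG, and its difference between RG and LGG did not pass (0.97, adjusted p = 0.0680). Among the genes tested, 800.0 were higher in both and 140.0 lower in both, where independent lists would share 440.0 and 23.7, and 2 changed in opposite directions. These counts rest on single libraries as those of RG against PBS do. They were 409 and 27 without PBS mouse 1, 40.0 and 0 without PBS mouse 3, 122 and 2 without PBS mouse 5, 135 and 14 without RG mouse 2, 156 and 18 without RG mouse 3, and 1265 and 280.0 without RG mouse 4, while 76 were lower in both without PBS mouse 4. With PBS mouse 1, RG mouse 2 and RG mouse 5 left out together no gene was shared (limma), since none passed for RG, where 965 had an unadjusted p under 0.05. The effects had a correlation of 0.741 across genes, with a jackknife SD of 0.118. Simulations of unchanged groups that share their PBS libraries gave a mean of 0.464, and 14 of 100 reached the observed value, so the correlation alone does not set the groups apart from this. With PBS libraries split between the comparisons the correlation had a median of 0.671 (range 0.565 to 0.789 in 20 splits), but the smaller groups left a median of 0 genes higher in both (limma, highest 39). The covariance of the effects was 0.364, against a mean of 0.0372 and a highest value of 0.0893 in the simulations, and it exceeded that mean by 0.327. The simulations left LGG unchanged as well, and a large LGG effect alone can raise the covariance. They also left out any choice of listed genes by their difference, so this excess does not show a shared effect. With median-of-ratios scaling 39 genes were higher in both and 568 lower in both.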

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

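In groups of 5 libraries, a value was picked out where its gap to the nearest other library exceeded 0.71 of the whole range of the group. For single genes the rule was applied to log2(TPM + 1), and the values below are given in TPM. This found 21 values in 270 groups, where chance gives about 13.5. The look at Kap and the inclusion of the ribosomal and defensin shares were chosen after results were seen, the other tests in this part were not. No explanation of these values was tested.

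Of the library measures, the listed genes of PBS mouse 2 summed to 58.6% of all TPM against 64.1 to 65.5% in the other PBS mice. The 10 highest genes of LGG mouse 4 held 9.78% against 7.02 to 7.63% in the other LGG mice. Of the list means of log2(TPM + 1), T cells in RG mouse 2 stood at 5.22 against 1.53 to 2.05, endothelium and lymphatics at 4.45 in the same mouse against 2.35 to 2.75, and colonic epithelium in RG mouse 3 at 4.90 against 2.91 to 3.33. Enteroendocrine cells stood at 4.31 in RG mouse 5 against 4.71 to 4.83, xenobiotic response genes at 5.87 in PBS mouse 2 against 5.13 to 5.31, and endothelium and lymphatics at 2.76 in PBS mouse 4 against 2.35 to 2.42. Paneth cells stood at 10.78 in PBS mouse 5 against 10.53 to 10.59, and tight junction genes at 7.25 in LGG mouse 4 against 7.11 to 7.14.

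Of the named genes, only the sentinels and those with the largest changes were searched, so others, such as Cd3d and Lat in RG mouse 2, are not in the count. Ang4 was at 4409 TPM in PBS mouse 1 against 974 to 1235 in the other PBS mice, and Defa41 at 1824 TPM in RG mouse 5 against 645 to 834. Defa31 was at 56.5 TPM in PBS mouse 4 and listed at 0 in the other PBS mice. Ces2a was at 78.8 TPM in PBS mouse 2 against 23.4 to 31.3, and Fmc1 at 209 TPM in the same mouse against 287 to 325. In LGG mouse 4, Slc2a5 was at 28.1 TPM against 81.7 to 113, Nr1d2 at 25.6 against 35.9 to 39.7 and Rpl41 at 2786 against 3937 to 4505. Gpr39 was at 31.2 TPM in LGG mouse 2 against 12.7 to 14.6, Fmc1 at 126 in LGG mouse 3 against 152 to 157, and Fkbp11 at 6.76 in RG mouse 5 against 12.7 to 15.1. Outside the genes tested, Kap was at 8.21 TPM in RG mouse 5 and listed at 0 in the other 14 libraries.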

How the results depend on the processing

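The tests with sample quality weights, a stricter filter, the length and GC trend removed, 3 libraries left out together, the midpoint of the sparse window as zero, camera with median-of-ratios scaling, and library measures with each library left out were chosen only after the results were seen. For the differences given here the cause was not tested.

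For RG against PBS, 948 genes changed, 804 higher and 144 lower. Changed, higher and lower genes were 612, 42 and 570.0 with median-of-ratios scaling, 583, 115 and 468 with upper-quartile scaling, 315, 279 and 36 with the length and GC trend removed, and 383, 343 and 40.0 with only the 2 groups in the fit. They were 0, 0 and 0 with PBS mouse 1, RG mouse 2 and RG mouse 5 left out together (limma, 965 at an unadjusted p under 0.05), and sample quality weights gave 286 lower genes. With the mouse number as a replicate block they were 174, 165 and 9, but the numbers do not pair the mice, since correlations of same-number libraries exceeded 0.1 in 1 of 5, 2 of 5 and 1 of 5 pairs in the 3 comparisons. With 1 library left out, changed genes ranged from 40.0 (PBS mouse 3) to 1594 (RG mouse 4), higher genes from 40.0 to 1278 and lower genes from 0 to 316.

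For LGG against PBS, 582 genes were lower, and 1391 with median-of-ratios scaling, 1388 with upper-quartile scaling and 1366 with the midpoint of the sparse window as zero. With 1 library left out, changed genes ranged from 2423 to 2612, higher genes from 1923 to 1985 and lower genes from 487 to 668. For RG against LGG, 289 genes were higher and 1887 lower, and these were 1088 and 1057 with median-of-ratios scaling, 1242 and 554 with upper-quartile scaling, and 522 higher with sample quality weights. With 1 library left out, changed genes ranged from 2017 to 2281, higher genes from 209 to 415 and lower genes from 1807 to 1906.

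Lists passing camera numbered 4 for RG against PBS, 7 for LGG against PBS and 13 for RG against LGG. With the correlation estimated per list they were 0, 0 and 0 (camera, lowest adjusted p = 0.773, 0.626 and 0.298). They were 7 with fry, 7 with median-of-ratios scaling and 10 with the length and GC trend removed for RG against PBS, 18 with fry and 11 with median-of-ratios scaling for LGG against PBS, and 7 with the 3 libraries left out for RG against LGG. With 1 library left out they ranged from 3 to 7, from 4 to 9 and from 8 to 13. Of the lists passing fry, 2, 6 and 9 also passed camera in the 3 comparisons.

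Genes higher in both RG and LGG numbered 800.0, and 140.0 were lower in both. These were 0 and 0 with PBS libraries split (limma, median of 20 splits), 39 and 568 with median-of-ratios scaling, 109 and 468 with upper-quartile scaling, 274 and 36 with the length and GC trend removed, 338 and 34 with only the 2 groups in the fit, 162 and 7 with the replicate block, and 0 and 0 with the 3 libraries left out, and quality weights gave 248 lower. With 1 library left out they ranged from 40.0 to 1265 and from 0 to 280.0. The correlation of 0.741 was 0.607 with the length and GC trend removed and 0.641 to 0.774 with 1 library left out. The planned tests of library measures that passed stayed at 6 with each library left out, and the ribosomal and defensin shares were not refitted that way.

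Some named results turned direction. Lyz1 in RG against PBS, 0.03, was -0.31 with median-of-ratios scaling, -0.25 with upper-quartile scaling, and -0.08, -0.11 and -0.06 without PBS mouse 1, RG mouse 1 and RG mouse 3. Reg3g in LGG against PBS was -0.59 and -0.70 with these scalings and -0.29 with the midpoint as zero, and Ddx58 in RG against LGG was 0.0549 with upper-quartile scaling. With the length and GC trend removed, LGG against PBS gave mt-Nd4l 2.93, mt-Nd1 1.52, mt-Nd2 1.48, mt-Co3 1.51, Reg3b 0.84, Tff3 0.37 and Spink4 0.0774, and RG against LGG gave Spink4 -0.20, Hba-a2 -0.18, Tff3 -0.38, Klrd1 -0.57, mt-Nd6 -1.47, mt-Nd4l -1.78, mt-Nd5 -0.0165, mt-Nd2 -0.61 and Ccl5 -0.60. The list of mitochondrially encoded genes turned with it, to adjusted p = 0.0448 in LGG against PBS and 0.205 in RG against LGG. In RG against LGG, Cd3d, Lat, Ccl5 and Lyve1 were -0.0718, -0.22, -0.23 and -0.0212 with the 3 libraries left out. Without RG mouse 2, Cd3d, Lat and Ccl5 were -0.00874, -0.23 and -0.30, and with quality weights Lat, Ccl5 and Lyve1 were -0.18, -0.00898 and -0.0512. With 1 library left out, the highest values were 0.27 for Lyz1 without RG mouse 5, 0.97 for Cd3d without RG mouse 3, and 0.85 for Lat and 0.64 for Ccl5 without RG mouse 4.

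Count-based tests, sample weights made for counts and a sex term were not run, since the deposit holds no counts and no sex-linked gene.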

Other observations

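Of the tests in this part, those of reads moved between defensins as a cause of the Paneth result, of a more proximal piece of intestine, of the broad rise and of the clock genes were chosen only after the results were seen.

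Genes of several other lists were higher after colonization on the deposited scale. Among tryptophan uptake genes, the amino acid transporter genes Slc6a19 (0.78 and 2.13) and Slc3a2 (0.90 and 2.43) rose with RG and with LGG, by both adjustments. Of 4 serotonin genes Slc6a4 rose with RG (0.85), with 3 higher when adjusted over the list alone, and all 4 rose with LGG by both adjustments, including the synthesis enzyme Ddc (1.65) and the degrading enzymes Maoa (1.79) and Maob (2.29). Of 7 unfolded protein response genes 4 rose with RG and 6 when adjusted over the list alone (camera adjusted p = 0.0968), among them the chaperone Hspa5 (0.83), and all 7 rose with LGG by both adjustments (median 1.63, camera adjusted p = 0.0837). Of 12 lipid absorption genes 6 rose with RG and 8 when adjusted over the list alone, and with LGG 10 rose, including the lipid transfer gene Mttp (2.47) and Apob (2.25), and 1 fell, the colipase gene Clps (-2.92). All 6 cholesterol synthesis genes rose with LGG by both adjustments (median 1.57, camera adjusted p = 0.104). The increases with RG depended on the scale. With median-of-ratios scaling none of the tryptophan, serotonin, unfolded protein response or lipid absorption genes passed for RG against PBS (limma), 2, 1, 3 and 0 of them had an unadjusted p under 0.05, and the medians of the lists were 0.44, 0.24, 0.37 and 0.20. With upper-quartile scaling 1 serotonin gene and 1 unfolded protein response gene passed. For LGG against PBS, median-of-ratios scaling left all 4 serotonin, all 7 unfolded protein response and all 6 cholesterol synthesis genes higher, and of the lipid absorption genes 9 higher and 2 lower.

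Both tested crypt stem cell genes, Axin2 (0.84 and 1.14) and Clca4b (0.71 and 2.40), rose with RG and LGG. Of 6 tuft cell genes 5 rose with LGG by both adjustments, including the taste channel Trpm5 (1.53), and with RG 1 rose and none when adjusted over the list alone. Of 5 enteroendocrine genes 2 rose with LGG, Chga (1.48) and Scg2 (1.32), while the median of the list was -0.26 and its mean 0.391. Of 4 vitamin A genes 3 rose with LGG, including Retsat (2.13) and Aldh1a1 (1.54). Of 4 MHC class II genes 1 rose with LGG, H2-DMa (1.28), and none when adjusted over the list alone. With median-of-ratios scaling Axin2 (0.54) still passed for RG against PBS and Clca4b (0.37, adjusted p = 0.284) did not, and no tuft cell gene did (limma, 2 with an unadjusted p under 0.05). For LGG against PBS both stem cell genes passed with that scaling, 5 tuft cell genes were higher and 1 lower, 2 enteroendocrine genes were higher and 3 lower, 2 vitamin A genes were higher, and no MHC class II gene passed (limma, 0 with an unadjusted p under 0.05).

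Other splits of the same 10 libraries, 100 per comparison with the real split included, gave at most 609 changed genes for RG against PBS, 1468 for LGG against PBS and 1707 for RG against LGG. The real values were 948, 2514 and 2176, and only the real split, 1 of 100 in each, reached them. Chance cannot be excluded from this, because the genes in the table look chosen by their difference between LGG and PBS, which favours the real split. The high counts of some other splits, in which the third group was kept as it is, are a property of these libraries that was not examined further.

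Paneth cell transcripts were low in LGG, with a median of -3.79 over 18 genes. A trend on transcript length and GC content was not the whole cause, since the median was still -1.75 (SE of the list mean 0.141) with the trend removed. Reads moved among listed defensins would leave their summed TPM equal, but the lowest PBS sum was 3.75 times the highest LGG sum. Reads moved to defensins outside the listed genes would lower the sum, and this was not tested. Defa31, which has 100% of its 31-base words in Defa23, may have gained reads in LGG. A more proximal piece of intestine in LGG would lower ileum genes, and the ileum-biased list lay 0.362 (SE 0.130) above the median of all genes. Yet the 4 tested jejunum genes lay higher still, 0.996 above it, which that test did not take in. The ileal genes Fabp6, Slc10a2 and Fgf15 were not listed, and the genes behind that median look chosen by their difference between LGG and PBS. The test therefore cannot decide, and a more proximal piece stays open. A more distal piece, towards the colon, was not tested and stays open, as does a loss of Paneth cells or of their transcripts with LGG, since cell numbers were not measured. The colonic list had a median of 1.59, where that of all genes tested was 1.17, and did not pass camera (adjusted p = 0.825). All 8 tested ileum-biased genes rose as well, with a median of 1.53, while LGG mouse 4 was highest in Slc26a3 (418 TPM).

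The listed genes rose broadly in LGG, with a median of 1.17. The TPM freed by lower defensins would raise all other genes by 0.170, too little by itself for that rise. Ribosomal protein genes also fell, from 18.2% of all TPM in PBS to 8.44% in LGG, and were not in this sum. A wider shift in composition was present, since the listed genes fell from 63.8% of all TPM in PBS to 50.1% in LGG. How much of the rise this shift gives was not tested. A candidate explanation is transcript length, whose rank correlation with the difference was 0.338 over 3310 genes without ribosomal, mitochondrial, respiratory chain and defensin genes and 0.405 over all. With the length and GC trend removed the median was 0.75 and 2687 genes changed, 2274 of them higher, but that correction keeps the mean of each library, so it does not test the level of the rise. Another is that genes were listed by the size of the difference between LGG and PBS, since the sparse window of ratios held 1.53% of the genes an even spread gives. Both stay open, and a biological rise of these transcripts was not tested.

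Clock genes were higher in LGG and in RG, with Dbp at 3.90 and 1.83. For LGG against PBS the median of the clock list was still 1.23 (SE of the list mean 0.617) with median-of-ratios scaling. That of all genes tested was 0.40. This scaling assumes that most listed genes are unchanged, and the list did not pass camera on the deposited scale (adjusted p = 0.157). The test therefore cannot decide whether the broad rise alone accounts for the clock genes. For RG against PBS the median of the clock list was 0.88 with median-of-ratios scaling, where that of all genes tested was 0.07. The broad rise was not tested as its cause. A difference in time of day at collection may be the cause for LGG, where Nfil3, whose phase is opposite to that of Dbp, was at -0.60 (SE 0.325), lower by more than 1 SE but with limma adjusted p = 0.111, while for RG against PBS it was at -0.30 (SE 0.325, adjusted p = 0.446), within 1 SE. The labels record no time of day, so this stays open beside an effect of the bacteria. Clock genes also varied with mouse number within PBS, where no bacteria were given. In PBS mice 1 to 5, Nr1d1 was at 6.37, 8.67, 14.3, 18.0 and 18.5 TPM. Nfil3 was at 17.2, 14.4, 7.30, 9.92 and 7.95 TPM in the same mice. Colonization cannot account for that drift, and the order of collection is not given. In LGG mice 1 to 5 Nfil3 did not fall in that order, at 6.56, 2.56, 7.36, 8.99 and 11.8 TPM.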
